A study of Homo sapiens with 27 samples.

How the data were processed

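RNA sequencing libraries came from 3 established human breast cancer cell lines grown as stable lines with an empty vector or a ROR2 plasmid, and each of the 27 libraries was placed in 1 of 9 groups of 3 from the labels alone. The siCTL group rests on the treatment field of its 3 samples, since their titles and columns name no siRNA and differ from those of untreated ROR2 cells only in lacking a tag. No column of the tables was left unused. Per the labels' protocols, MCF-7 RNA was extracted with Trizol and made into libraries with a TruSeq Stranded Total RNA kit, whereas BT-474 and SK-BR-3 RNA was extracted with High Pure columns and made into libraries with mRNA enrichment and a directional NEBNext Ultra II kit. The labels name the replicates but do not say that they are separate cultures, so p-values measure only the spread between these samples, which may be technical.

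The MCF-7 table holds expected counts per gene, estimated counts that need not be whole, as the authors deposited them; between 21.9% and 24.7% of the values in each library were not whole, and they were rounded to whole numbers here. The table of BT-474 and SK-BR-3 holds whole-number counts per gene as deposited by the authors, with no normalization. Per the submitters' processing notes, the tools were CASAVA 1.8.2, FastQC, STAR, RSEM, HISAT2 2.1.0 and featureCounts 1.6.3, with the GRCh38 or hg38 genome. The deposited tables are named for RSEM in MCF-7 and for featureCounts in BT-474 and SK-BR-3. The aligner of each, the strand setting of the counting and the annotation are not given in the sources used here, so reads of overlapping or antisense genes may not be told apart, and reads shared by near-identical genes such as histones or RPS17 make those counts uncertain. Reads from the ROR2 plasmid and from the chromosomal gene are not distinguished. The kits and counting differ between the tables, so each was tested separately and no level was tested across them. Calls, and for neighbouring genes the medians of log2 fold changes over windows, were compared between lines.

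Total counts were 39586714 to 65447311 in MCF-7, 18698131 to 22001678 in BT-474 and 19448626 to 22229936 in SK-BR-3, and mitochondrially encoded genes took 4.34% to 6.64%, 6.65% to 8.50% and 3.87% to 5.84% of them. Gene symbols were found for 56590 of 60279 gene identifiers in the MCF-7 table (93.9%) and for 57447 of 58051 in the other (99%), and coordinates come from the GENCODE annotation of GRCh38. A gene with 0 counts in a group was set at a floor of 3 counts over the group, and ratios against 1 to 3 counts are given with a 95% interval. Floors and intervals cover counting error only.

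Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM factors (0.948 to 1.06 in MCF-7, 1.03 to 1.06 in BT-474 and 0.929 to 0.995 in SK-BR-3), the filterByExpr filter at a minimum count of 10, and Benjamini-Hochberg adjustment over all genes tested, called at 0.05. All 15 MCF-7 libraries entered 1 fit and the other 12 libraries another, with a coefficient per group and no block. The 8 comparisons were ROR2 against vector in each line, siWNT11 against siCTL and siCTL against untreated in MCF-7 ROR2 cells, siWNT11 against untreated in MCF-7 vector cells, the interaction of siWNT11 with ROR2, and the difference of the ROR2 effects in BT-474 and SK-BR-3. Calls shared by lines, or opposed between ROR2 and siWNT11, were counted beside the number that independent lists of the same sizes would share.

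Gene lists, 20 in all and of at least 5 tested members each, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. At the estimated correlation the calls that held were interferon response with siWNT11 in vector cells and estrogen receptor targets and identity markers with ROR2 in BT-474, the last 2 only with the library labelled SK-BR-3 vector replicate 1 in the fit. Those last 2 lists share ESR1 and PGR. All symbols of the lists were matched except that 22 of 24 were in the YAP and TAZ list and 18 of 36 in the histone list, where the others are older or newer symbols of the same genes. Genes named in the text were ROR2 and WNT11; the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and that had at least 5 CPM in the higher group, without symbols of clone or pseudogene style, a pattern that also takes in coding genes whose symbols end in P and a digit; up to 4 called members of each called list and up to 2 of the others; up to 5 each way for an interaction; and up to 10 for shared or opposed calls. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined; those added later are named as such where they are given.

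The scripts were tested on simulated counts with known changes. In the simulated MCF-7 ROR2 comparison (20007 genes) 19.4%, 34.3% and 72.7% of genes changed 1.5-fold, 2-fold and 4-fold were called, with 3 false calls, and in the simulated BT-474 comparison (15538 genes) 29.9%, 62.7% and 81.8%, with 7. In the simulated interaction in MCF-7 (19981 genes) the shares were 1.49%, 11.9% and 62.1%, and for the difference between BT-474 and SK-BR-3 (15533 genes) 5.97%, 29.9% and 69.7%. Camera found the shifted list in all 8 simulated comparisons and called 1 other list in 2 of them. Genes were drawn independently of each other and without pairing by replicate number, so the simulations do not test the preset correlation. Only 67, 67 and 66 genes were changed at the 3 folds, far fewer than the 5500 called in the real MCF-7 ROR2 comparison. The shares called therefore hold for comparisons with few changed genes and may differ where many genes change.

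The alternatives were RLE size factors, no filter or a minimum count of 50, DESeq2 1.42.0, limma-voom, leaving out mitochondrial and the 20 most abundant genes, the replicate number as a block, only the groups compared in the fit, untreated cells as control, stricter thresholds and leaving out each library. Libraries with the same replicate number deviated together from their group means in siWNT11 against siCTL (correlations across genes of 0.244 to 0.520), siCTL against untreated (0.249 to 0.555), siWNT11 in vector cells (0.222 to 0.609) and BT-474 (0.242 to 0.450), so the numbers, which the labels give, were taken to pair these libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.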

Results

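Messenger RNA levels were measured by RNA sequencing in 3 human breast cancer cell lines, each carried as stable cells with an empty vector or with a plasmid for ROR2, a single-pass receptor of noncanonical Wnt signalling. MCF-7 and BT-474 express the estrogen receptor, and BT-474 and SK-BR-3 carry an amplified ERBB2 gene. The 27 libraries fell into 9 groups of 3. In MCF-7 there were 5 groups: vector cells, vector cells given an siRNA against WNT11 (siWNT11), ROR2 cells, and ROR2 cells given siWNT11 or a control siRNA (siCTL), with each siRNA used at 10 nM for 72 h. The siCTL libraries are known as such from their treatment field, since their titles name no siRNA. BT-474 and SK-BR-3 each had a vector group and a ROR2 group. Total counts per library were 39586714 to 65447311 in MCF-7, 18698131 to 22001678 in BT-474 and 19448626 to 22229936 in SK-BR-3. In BT-474 vector cells ERBB2 stood at 8667 ± 979 CPM (counts per 1e6 of the TMM-scaled library size over tested genes; mean ± SD, n = 3 in this and every other group) and ESR1, the estrogen receptor gene, at 24.7 ± 6.76 CPM. MCF-7 values come from a separate table made with other tools and another library kit, so levels are set against each other only within a table. CDH1, the E-cadherin gene, had 163 ± 56.1 CPM in BT-474 vector cells and 2 counts in all over the 3 libraries labelled SK-BR-3 vector.

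ROR2 (ENSG00000169071, GRCh38 chromosome 9, 91563091 to 91950162) followed the labels in 26 of the 27 libraries. In MCF-7 it stood at 6.43 ± 4.56 CPM in vector cells and 1542 ± 380.1 in ROR2 cells. It was 3.95 ± 3.02 in vector cells given siWNT11, 1988.5 ± 195 in ROR2 cells given siCTL and 1692 ± 453 in ROR2 cells given siWNT11. In BT-474 it had 2 counts in all in vector cells and 457 ± 71.8 CPM in ROR2 cells, a ratio of 1.46e+04 (95% interval for counting error 4.04e+03 to 1.21e+05). In SK-BR-3 the 3 ROR2 libraries held 3965, 3963 and 4668 CPM. The libraries labelled SK-BR-3 vector replicates 2 and 3 held 2.96 and 2.17 CPM. The library labelled SK-BR-3 vector replicate 1 held 3989 CPM, which goes against its label. The gene counts and list calls of the fit with SK-BR-3 are therefore also given without that library, a choice made after its ROR2 level was seen.

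WNT11 (ENSG00000085741, GRCh38 chromosome 11, 76186325 to 76210736), a secreted ligand that can act through ROR2, rose with ROR2 in MCF-7 from 0.724 ± 0.349 to 7.44 ± 2.96 CPM (log2 fold change 3.39, SE 0.40, edgeR quasi-likelihood adjusted p = 5.74e-05). It stood at 8.11 ± 1.78 CPM with siCTL and 1.56 ± 0.195 with siWNT11 in ROR2 cells, and at 0.251 ± 0.0537 in vector cells given siWNT11. BT-474 held 4.74 ± 3.66 CPM in vector cells and 6.50 ± 2.25 in ROR2 cells, a difference within the spread between replicates (log2 fold change 0.45, SE 0.49, edgeR quasi-likelihood adjusted p = 0.672). In SK-BR-3 the gene was near the detection limit, with 3 counts in all in the libraries labelled vector and 2 in the ROR2 libraries.

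**Figure D1:**
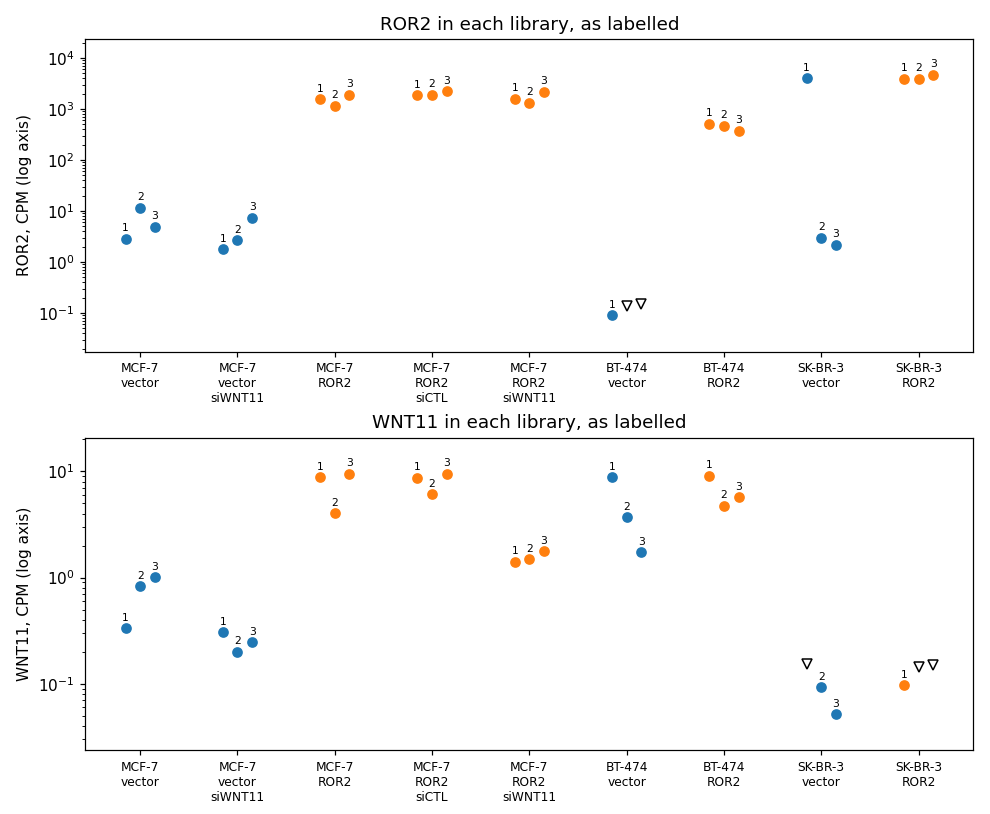
ROR2 (top) and WNT11 (bottom) in each of the 27 libraries, in CPM on a log axis, with the groups of 3 along the horizontal axis, the replicate number above each point, and open triangles for a count of 0 drawn at the level of 3 counts. The library labelled SK-BR-3 vector replicate 1 holds 3989 CPM of ROR2, beside 2.96 and 2.17 CPM in the other libraries with that label.

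The comparison of MCF-7 ROR2 cells with MCF-7 vector cells, both without siRNA, asks which genes move with ROR2, that is, differ between these stable lines. The labels name no separately derived stable lines within a group. An effect of ROR2 can therefore not be told apart from other differences between the stable lines, here or in BT-474 and SK-BR-3. The rises included LRRTM3, a synaptic adhesion protein gene (51.2 ± 1.23 against 0.222 ± 0.20 CPM, log2 fold change 7.95, SE 0.34), the atypical cadherin gene FAT1 (5.80, SE 0.44), the nuclear receptor gene HNF4G (23.1 ± 1.43 against 0.569 ± 0.138 CPM, log2 5.37, SE 0.18) and the growth factor gene TGFB2 (5.04, SE 0.33). NT5E, which encodes the ecto-enzyme CD73, rose from 1.28 ± 0.755 to 37.8 ± 10.2 CPM. The adenosine receptor gene ADORA1 rose from 0.647 ± 0.0701 to 12.3 ± 1.45 CPM. Among the falls, LCN2, the lipocalin that binds bacterial siderophores, fell from 82.9 ± 32.2 to 0.483 ± 0.172 CPM (log2 -7.45, SE 0.44). The complement genes CFB (85.3 ± 17.1 to 0.743 ± 0.122 CPM) and C3 (17.1 ± 2.46 to 0.631 ± 0.239 CPM) fell as well. S100A8 and S100A9, which encode the subunits of calprotectin, fell from 18.3 ± 2.85 to 0.123 ± 0.0306 CPM and from 43.1 ± 12 to 0.654 ± 0.0187 CPM. ACE2 (log2 -4.50, SE 0.30), TMEM45A (-4.94, SE 0.89) and the kinase gene NEK9 (20.9 ± 1.96 to 1.05 ± 0.131 CPM) completed the 8 falls named by the rule. The largest edgeR quasi-likelihood adjusted p among these genes was 2.75e-05 for the rises, for NT5E, and 0.00147 for the falls, for TMEM45A. In each gene all 3 libraries of one group lay beyond all 3 of the other. In all, 5500 of 20404 genes passed an edgeR quasi-likelihood adjusted p of 0.05, 2564 higher and 2936 lower in ROR2 cells, of which 842 and 1212 differed more than 2-fold.

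Genes of hypoxia and glycolysis, NF-kB target genes and histone genes were lower in MCF-7 ROR2 cells. Of 24 hypoxia and glycolysis genes 17 fell and 0 rose (19 fell when adjusted over the list alone; median log2 fold change -1.40), among them the hexokinase gene HK2 (238 ± 68.5 to 68.2 ± 9.59 CPM), AK4 (log2 -1.63, SE 0.27), PDK1, which restrains pyruvate oxidation (-2.09, SE 0.39), and the mitophagy receptor gene BNIP3 (-2.25, SE 0.42). Of 16 NF-kB target genes 12 fell and 0 rose (12 when adjusted over the list alone; median -1.37), among them TNF (1 ± 0.191 to 0.0388 ± 0.00643 CPM), the apoptosis inhibitor gene BIRC3 (log2 -3.51, SE 0.37), the adhesion molecule gene ICAM1 (23.3 ± 3.03 to 3.58 ± 0.231 CPM) and TNFAIP2 (-3.30, SE 0.22). Of 17 replication-dependent histone genes 11 fell and 0 rose (13 when adjusted over the list alone; median -0.86), including H2BC5 (-1.62, SE 0.18), H2AC6 (-1.11, SE 0.12), H4C8 (-1.41, SE 0.25) and H2BC8 (-1.57, SE 0.30). Histone genes have near-identical copies, so the share of each is uncertain, and these 4 lie in a stretch of chromosome 6 whose genes were lower together (24171756 to 26453415, median -1.06). That stretch counts these histone genes among its 51, so its median is not separate from their fall. The camera adjusted p was 1.31e-07 for hypoxia and glycolysis, 1.92e-10 for NF-kB and 1.17e-05 for histones. With an estimated correlation none of these calls held, at camera adjusted p = 0.422, 0.0769 and 0.198.

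The hypoxia and glycolysis genes also differed between replicates of the vector group, with mean log2 CPM of 7.78, 7.43 and 6.14 in vector replicates 1, 2 and 3 against 6.11, 5.46 and 5.63 in the ROR2 replicates. Without vector replicate 1 the number of falls in this list was 10. It was 23 without the third replicate of every MCF-7 group, left out after seeing the data because these libraries stand apart. The 11 histone falls became 6 without vector replicate 1 or ROR2 replicate 2, and 7 without vector replicate 2 or ROR2 replicate 3.

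Actin and Rho GTPase genes, YAP and TAZ target genes, cholesterol synthesis genes and cell cycle genes were higher in MCF-7 ROR2 cells. Of 39 Rho and actin genes 22 rose and 3 fell (23 and 4 when adjusted over the list alone; median log2 fold change 0.44), including the Cdc42 effector gene CDC42EP3 (3.16, SE 0.31), the actin-binding protein gene TAGLN (5.72 ± 1.09 to 22.7 ± 6.48 CPM), RND1 (1.79, SE 0.21) and vinculin, VCL (60.6 ± 3.67 to 97.1 ± 8.91 CPM). Of 19 YAP and TAZ target genes 13 rose and 2 fell (the same numbers when adjusted over the list alone; median 0.66), with CCN2, a matricellular protein gene, at log2 3.43 (SE 0.36) and CRIM1 at 1.10 (SE 0.14) beside TGFB2 and NT5E. Of 23 cholesterol synthesis genes 11 rose and 1 fell (13 and 1 when adjusted over the list alone; median 0.39), with the late-pathway enzyme gene DHCR24 at 181 ± 8.91 against 308 ± 12.1 CPM, IDI1 at log2 0.73 (SE 0.09), FDFT1 at 0.59 (SE 0.10) and CYP51A1 at 0.58 (SE 0.08). Of 30 cell cycle genes 10 rose and 0 fell (12 and 0 when adjusted over the list alone; median 0.37), including the ribonucleotide reductase subunit gene RRM2 (223 ± 23.4 to 435 ± 14.6 CPM), MYBL2 (0.68, SE 0.12), TYMS (0.54, SE 0.10) and CCNA2 (0.44, SE 0.07). The camera adjusted p was 4.3e-07 for both the Rho and the YAP and TAZ lists, 1.17e-05 for cholesterol synthesis and 7.25e-05 for the cell cycle. With an estimated correlation the calls were lost, at camera adjusted p = 0.0769, 0.137, 0.0769 and 0.16 in that order. Without vector replicate 2 the cell cycle count was 5.

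Ligands of the ERBB receptors split in MCF-7. AREG, the amphiregulin gene, rose from 0.825 ± 0.0864 to 24.1 ± 2.26 CPM and betacellulin, BTC, from 0.0286 ± 0.0164 to 1 ± 0.183 CPM. EREG, the epiregulin gene, had 0 counts in vector cells and 165 in ROR2 cells, at least 52.5-fold higher against a floor of 3 counts over the group. TGFA fell from 19.8 ± 3.93 to 11.2 ± 1.12 CPM. Of the 13 measured genes of the ERBB list, which was written with ERRFI1 and GRB7 beside receptors and ligands, 4 rose and 4 fell, with the same numbers when adjusted over the list alone. Their median log2 fold change was -0.01, the same with EREG at its bound. The mean, which takes EREG at its fitted value, was 1.28, and camera called the list up at adjusted p = 0.00611, or 0.0769 with an estimated correlation.

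The other 12 lists were not called by camera in this comparison, although members changed in both directions in all but the interferon and mitochondrial lists. Of 39 noncanonical Wnt and planar polarity genes 9 rose and 9 fell (camera adjusted p = 0.29). Of 19 beta-catenin target genes 3 rose, with the Wnt inhibitor gene APCDD1 at log2 1.93 (SE 0.26), and 4 fell, with the hyaluronan receptor gene CD44 at 403 ± 66 to 67.4 ± 3.32 CPM (0.636). Of 30 epithelial genes 5 rose, among them the tight junction gene CLDN1 (log2 3.70, SE 0.36), and 8 fell, among them the mucin gene MUC1 (213 ± 24.9 to 13.1 ± 2.35 CPM), at camera adjusted p = 0.352. Of 24 mesenchymal genes 6 rose, with the urokinase gene PLAU at log2 2.74 (SE 0.19), and 8 fell, with TWIST1 at -5.19 (SE 0.55), at camera adjusted p = 0.906. Of 26 estrogen receptor target genes 3 rose and 9 fell, with CXCL12 at -1.32 (SE 0.12), at camera adjusted p = 0.399. Of 36 interferon response genes 0 rose and 6 fell, with IFI44 at -3.66 (SE 0.59) and IFI44L at -3.33 (SE 0.78), at camera adjusted p = 0.0534. This camera adjusted p became 0.000694 without the third replicates and 0.00421, 0.05 and 0.000156 without vector replicate 2, ROR2 replicate 2 or ROR2 replicate 3. Of 22 p53 target genes 8 rose, with PLK3 at 1.53 (SE 0.26), and 4 fell, with PMAIP1 at -1.09 (SE 0.17; 0.194). Of 26 immediate early genes 4 rose, with KLF6 at 17.6 ± 1.03 to 65.2 ± 1.77 CPM, and 5 fell, with the ERK phosphatase gene DUSP6 at -1.32 (SE 0.20; 0.508). Of 21 unfolded protein and stress response genes 4 rose, with the cystine transporter gene SLC7A11 at 1.21 (SE 0.17), and 4 fell, with DNAJC3 at -0.94 (SE 0.10; 0.906). None of 13 mitochondrially encoded mRNAs was called (0.906), and 2 of 7 leukocyte, endothelial and fibroblast markers rose and 3 fell (0.484; COL3A1 -1.76, SE 0.32). Of 9 cell line identity markers the androgen receptor gene AR rose (1.13, SE 0.18) while PGR fell (-0.60, SE 0.14) with 1 other (0.582).

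**Figure D2:**
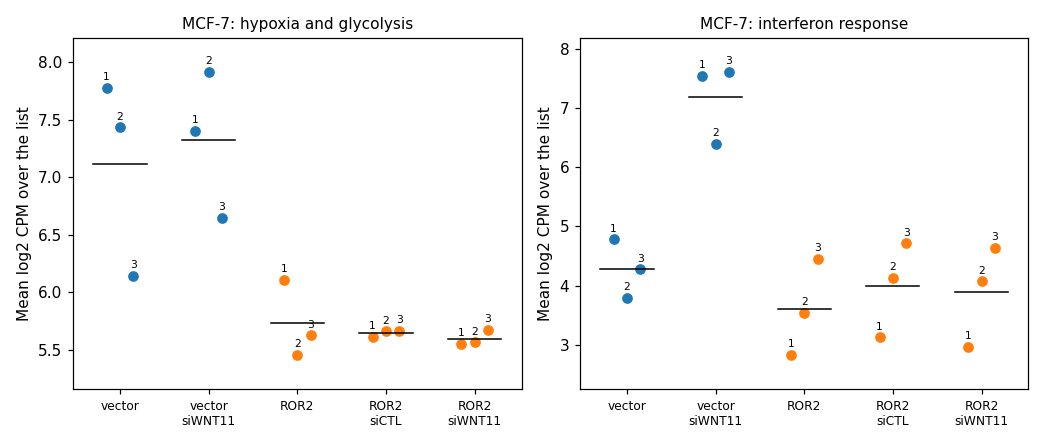
Mean log2 CPM over the hypoxia and glycolysis list (left) and the interferon response list (right) in each of the 15 MCF-7 libraries, with the 5 groups along the horizontal axis, replicate numbers above the points and group means as horizontal lines. Hypoxia and glycolysis genes lie at 7.78, 7.43 and 6.14 in the vector libraries and at 6.11, 5.46 and 5.63 in the ROR2 libraries, and interferon genes at 7.55, 6.40 and 7.61 in vector cells given siWNT11.

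The comparison of siWNT11 with siCTL in MCF-7 ROR2 cells asks what depends on WNT11 when ROR2 is present. WNT11 fell 5.21-fold, from 8.11 ± 1.78 to 1.56 ± 0.195 CPM (log2 -2.38, SE 0.37, edgeR quasi-likelihood adjusted p = 0.0314), while ROR2 differed by less than its spread (log2 -0.23, SE 0.48). The other falls were led by MGAT1, which starts complex N-glycan synthesis (81.8 ± 9.09 to 24.7 ± 3.07 CPM, log2 -1.73, SE 0.15), the ubiquitin ligase gene RNF38 (30.6 ± 3.02 to 14.8 ± 0.934 CPM), GPAT3, an enzyme of glycerolipid synthesis (-1.03, SE 0.18), PLEKHA3 (-0.92, SE 0.10), the sialic acid activating enzyme gene CMAS (-0.75, SE 0.08), RRAS2 (-0.72, SE 0.08) and EVI5 (-0.70, SE 0.11). The rises were led by the endosomal syntaxin gene STX12 (22.1 ± 2.18 to 45.1 ± 1.13 CPM, log2 1.03, SE 0.08) and the tropomyosin gene TPM4 (562 ± 79.6 to 1028 ± 73.4 CPM), followed by ZNF267, SETD7, ZNF680, ZW10, MESD and MTM1 at log2 0.65, 0.65, 0.61, 0.55, 0.54 and 0.52. CASP7 (0.84, SE 0.15), HABP4 (0.71, SE 0.11) and G3BP2 (0.60, SE 0.06) rose within this range of sizes, but their symbols end in P and a digit, which the naming rule leaves out as pseudogene style. The largest edgeR quasi-likelihood adjusted p among these genes was 0.0465, for GPAT3.

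In this comparison 36 of 20404 genes passed an edgeR quasi-likelihood adjusted p of 0.05, 13 higher and 23 lower with siWNT11. The excess of falls was smaller in other settings: with RLE size factors 12 were higher and 14 lower, and without mitochondrial and the 20 most abundant genes 12 and 12. With the replicate number as a block 59 passed, 23 higher and 36 lower, and with only the 2 groups in the fit edgeR's quasi-likelihood test called 0, so not WNT11 either (711 at an unadjusted p under 0.05 in the full fit and 93 by DESeq2). WNT11 was the 1 noncanonical Wnt gene called and TPM4 the 1 Rho and actin gene. Camera called 0 of the 20 lists (adjusted p at least 0.505). Each of the 6 libraries supported part of the count. It was 9, 13 and 11 without siCTL replicate 1, 2 or 3 and 10, 11 and 12 without siWNT11 replicate 1, 2 or 3, and 3 without the third replicates. The interferon list was called without 4 of these libraries, upwards without siWNT11 replicate 1 or siCTL replicate 3 (camera adjusted p = 0.00458 and 0.0273) and downwards without siWNT11 replicate 3 or siCTL replicate 1 (0.00656 and 4.24e-06). Each of these 4 fits lacks 1 library of a pair and has no block. Within the pairs the list was slightly lower with siWNT11 (mean log2 CPM 2.97, 4.07 and 4.64 against 3.13, 4.13 and 4.72), and with the block it was not called (camera adjusted p = 0.726). Other lists were called without siWNT11 replicate 3 (beta-catenin 0.0274, epithelial 0.00157, YAP and TAZ 0.0274) and without siCTL replicate 3 (cell cycle 0.0194, mitochondrial 0.0341).

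Of the genes that moved with ROR2 in MCF-7, 10 moved the opposite way with siWNT11 in ROR2 cells. All 10 were higher with ROR2 and lower with siWNT11: WNT11, GPAT3, the small GTPase gene RRAS2, the chloride and proton exchanger gene CLCN5, CPNE1, the focal adhesion gene LIMS1, TMEM245, SPRYD3, the nucleoporin gene NUP50 and TSN. In the falling direction 0 genes were called with ROR2 and rose with siWNT11. Independent lists of these sizes would share 2.89 genes in the first pattern and 1.87 in the second. Another 4 genes moved the same way in both comparisons (3 higher, where 1.63 would be shared, and 1 lower, where 3.31 would be). These comparisons share no library. WNT11 is the target of the siRNA, so its place among the 10 only shows the knockdown. The other opposed genes also had negative log2 fold changes with siWNT11 in vector cells, from -0.80 for GPAT3 to -0.22 for CLCN5. In DESeq2 opposed and same-way calls were equal (19 and 19), and with untreated ROR2 cells as control, which both comparisons then share, they were 2 and 3. The 10 became 1, 2 and 1 without siWNT11 replicate 1, 2 or 3 and 1, 3 and 2 without siCTL replicate 1, 2 or 3. They became 20 with the replicate number as a block (16 and 4 in the 2 directions).

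The control siRNA itself was compared with untreated MCF-7 ROR2 cells. STX12 fell from 39.3 ± 1.26 to 22.1 ± 2.18 CPM (log2 -0.83, SE 0.08, edgeR quasi-likelihood adjusted p = 0.00294), and so did G3BP2, a stress granule protein gene named after its value was seen (log2 -0.58, SE 0.06, edgeR quasi-likelihood adjusted p = 0.0039). WNT11 (log2 0.12, SE 0.35) and ROR2 (0.37, SE 0.48) differed by less than their spread. The 2 genes were the only calls of edgeR's quasi-likelihood test among 20404, beside 1561 genes at an unadjusted p under 0.05, 154 calls by DESeq2, 5 by limma-voom and 76 with the replicate number as a block. The count was 4 without untreated replicate 1 and 1 without untreated replicate 2 or any 1 of the siCTL libraries. With only the siCTL and untreated groups in the fit, edgeR's quasi-likelihood test called no gene, so neither STX12 nor G3BP2.

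Camera called 6 lists with siCTL although no member was called over all genes. Unfolded protein and stress response genes (median log2 fold change 0.18, camera adjusted p = 4.22e-05), Rho and actin genes (0.16, 8e-05), immediate early genes (0.16, 0.00225), interferon response genes (0.36, 0.00284) and NF-kB target genes (0.29, 0.00524) were higher, and histones were lower (-0.25, 0.0114). Adjusted over the list alone, 1 unfolded protein gene, 2 Rho genes and 1 immediate early gene were higher and 1 Rho gene and 2 histone genes were lower. With an estimated correlation the camera adjusted p was 0.225 for the first 3 lists, 0.862 for interferon and 0.797 for NF-kB and histones. The interferon call was lost without untreated replicate 1 or siCTL replicate 3, each 1 library of a pair (camera adjusted p = 0.805 and 0.812), and was made with the block (0.0043). The NF-kB call was lost without siCTL replicate 2 (camera adjusted p = 0.0777), and the histone call without untreated replicate 1 or 3 or siCTL replicate 2 (0.333, 0.0707 and 0.0777).

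In MCF-7 vector cells, siWNT11 was compared with untreated cells, because the labels give no control siRNA in that background, so the comparison holds the act of transfection too. Interferon-induced genes rose: IFIT3, an antiviral protein gene, from 2.67 ± 1.71 to 154 ± 96.9 CPM (log2 5.82, SE 0.81), OAS2, which makes the activator of RNase L, from 12.3 ± 6.64 to 481 ± 296 CPM, and the GTPase gene MX2 from 0.977 ± 0.48 to 39.1 ± 28.9 CPM. So did CMPK2 (5.53, SE 0.93), XAF1 (5.43, SE 0.95), APOL3 (5.25, SE 0.82), TRIM22 (5, SE 0.70) and APOL6 (4.83, SE 0.72). The transcription factor gene STAT2 rose from 71.3 ± 12 to 219 ± 30.1 CPM, HERC5 from 20.8 ± 2.21 to 67.7 ± 9.45 CPM and OASL by 4.18 on the log2 scale (SE 0.57). Of 36 interferon response genes 21 rose and 0 fell (35 rose when adjusted over the list alone; median log2 fold change 2.51), at camera adjusted p = 1.03e-100, or 0.0234 with an estimated correlation. Mean log2 CPM over this list was 7.55, 6.40 and 7.61 in the siWNT11 libraries and 4.78, 3.79 and 4.28 in the untreated ones.

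The falls in vector cells were led by MGAT1 (92.6 ± 9.95 to 44.9 ± 2.04 CPM, log2 -1.04, SE 0.15), the mannosidase gene MAN1A1 (57.6 ± 8.87 to 32.7 ± 4.63 CPM), MAOA, PLEKHA3, EVI5, ATP8A1, RNF38 and TBCEL, the last with log2 -0.61 (SE 0.10), while TP53INP1 (-0.67, SE 0.13) was left out by its symbol. All 8 named by the rule had an edgeR quasi-likelihood adjusted p of at most 0.0253. WNT11 went from 0.724 ± 0.349 to 0.251 ± 0.0537 CPM, which did not pass (log2 -1.48, SE 0.44, edgeR quasi-likelihood adjusted p = 0.211). Cholesterol synthesis genes were higher as a list (median 0.14, camera adjusted p = 0.000121, 0.227 with an estimated correlation), with the LDL receptor gene LDLR up from 109 ± 2.30 to 145 ± 13.0 CPM, the 1 member called (4 higher and 1 lower when adjusted over the list alone). The unfolded protein list was higher (median 0.30, camera adjusted p = 9.52e-05, 0.242 with an estimated correlation), although its 1 called member, SEL1L of endoplasmic reticulum degradation, fell (log2 -0.46, SE 0.10). NF-kB target genes were higher (median 0.29, camera adjusted p = 0.0005, 0.579 with an estimated correlation) and mitochondrially encoded mRNAs lower (-0.23, 0.000793, 0.698 with an estimated correlation), with 0 members called in either (1 NF-kB target gene higher when adjusted over the list alone). Both calls were lost without siWNT11 replicate 3 (camera adjusted p = 0.0563 and 0.0846).

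Among 20404 genes 170 passed an edgeR quasi-likelihood adjusted p of 0.05 in vector cells, 134 higher and 36 lower. With only the siWNT11 and untreated vector groups in the fit this test called no gene (1836 at an unadjusted p under 0.05 in the full fit). With the replicate number as a block 395 passed, and cell cycle, hypoxia and immediate early genes were called as well (camera adjusted p = 0.0473 for each). The count was 94, 50 and 44 without vector replicate 1, 2 or 3, 44, 372 and 67 without siWNT11 replicate 1, 2 or 3, and 0 without the third replicates. The interferon genes called numbered 11, 6 and 5 without vector replicate 1, 2 or 3 and 8 and 10 without siWNT11 replicate 1 or 3, with the list called by camera each time. The hypoxia list was called without vector replicate 1 or 2 or siWNT11 replicate 3 (camera adjusted p = 5.35e-08, 0.0091 and 1.48e-06).

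Of the 36 genes that moved with siWNT11 in ROR2 cells, 12 of the falls were also called as falls in vector cells, where independent lists would share 0.041, and 1 rise, CASP7, was called in both, where 0.085 would be shared. With the replicate number as a block 24 falls were shared (0.251 by independent lists) and again 1 rise. This overlap was counted after the data were seen, and the comparisons share no library.

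**Figure D3:**
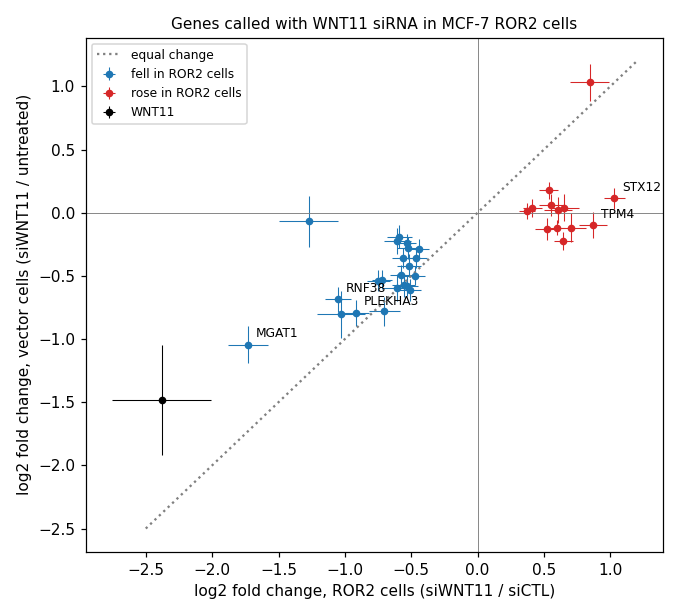
Log2 fold change with siWNT11 in MCF-7 vector cells (vertical, against untreated cells) against that in MCF-7 ROR2 cells (horizontal, against siCTL) for the 36 genes called in ROR2 cells, with standard errors as bars and a dotted line of equal change. The genes that fell in ROR2 cells lie below 0 in vector cells too, MGAT1 at -1.73 and -1.04, while STX12 (1.03 and 0.11) and TPM4 (0.87 and -0.10) lie near 0 in vector cells.

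Whether siWNT11 acted differently in ROR2 and vector cells was tested as an interaction, each against its untreated cells. The interferon genes differed as a list, with a median log2 difference of -2.30. In ROR2 cells the list stood at 2.97, 4.07 and 4.64 mean log2 CPM with siWNT11 and at 2.83, 3.54 and 4.46 untreated. Camera called the difference at adjusted p = 4.46e-72, but at 0.0702 with an estimated correlation, with 29 members lower when adjusted over the list alone and 0 over all genes. IFIT3 differed by -5.32 (SE 1.04, edgeR quasi-likelihood adjusted p = 0.239). Cholesterol synthesis genes (median -0.11, camera adjusted p = 0.000368, 0.296 with an estimated correlation) and mitochondrially encoded mRNAs (0.32, 4.79e-06, 0.791 with an estimated correlation) were called too. WNT11 (log2 difference -0.78, SE 0.58) and ROR2 (0.83, SE 0.70) did not pass the threshold. The edgeR quasi-likelihood test called 0 of 20404 genes, beside 981 at an unadjusted p under 0.05, 75 calls by DESeq2 and 1 by limma-voom. Without siWNT11 vector replicate 2 it called 66, and without vector replicate 1 or ROR2 replicate 1 it called 1.

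In BT-474, ROR2 cells were set against vector cells. Estrogen receptor target genes rose: TFF1, the trefoil factor gene, from 8.65 ± 3.85 to 42.9 ± 11.4 CPM (log2 2.31, SE 0.32, edgeR quasi-likelihood adjusted p = 0.0206), GREB1 from 25.6 ± 10.3 to 100.4 ± 27.7 CPM (1.97, SE 0.33), the progesterone receptor gene PGR from 31.4 ± 10.8 to 89.4 ± 16.4 CPM (1.51, SE 0.26), STC2 (1.26, SE 0.24) and the ubiquitin ligase gene SIAH2 (1.01, SE 0.16). ESR1 itself was 24.7 ± 6.76 and 42.1 ± 2.61 CPM and did not pass (log2 0.77, SE 0.17, edgeR quasi-likelihood adjusted p = 0.0502), but passed without the library labelled SK-BR-3 vector replicate 1 (0.76, SE 0.15, edgeR quasi-likelihood adjusted p = 0.0225). Of 25 measured estrogen receptor target genes 7 rose and 0 fell (11 and 2 when adjusted over the list alone; median 0.42), at camera adjusted p = 4.81e-06, or 0.0409 with an estimated correlation (0.0747 without the library labelled SK-BR-3 vector replicate 1). Cell line identity markers were higher as well, with 2 of 10 called (4 when adjusted over the list alone), PGR and the E-cadherin gene CDH1 (163 ± 56.1 to 303 ± 24.2 CPM), at a median of 0.55 and camera adjusted p = 0.00141, or 0.0409 with an estimated correlation (0.0666 without that library). This list shares ESR1 and PGR with the estrogen receptor target list, so the calls of these lists are not separate results.

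The other rises in BT-474 named by size included the cystatin gene CST1 (0.75 ± 0.247 to 5.48 ± 0.595 CPM) and the glycosyltransferase gene B4GALNT2 (log2 1.59, SE 0.32). The rest were the matrix protein gene TNC (9.70 ± 5 to 28.7 ± 5.65 CPM), ADAMTS1 (1.55, SE 0.29) and RPS17 (3.09, SE 0.63). RPS17 is a ribosomal protein gene with near-identical copies, so its level is uncertain, and it ranged widely between the ROR2 libraries (18.2 ± 14 CPM). BRINP2 (2.32, SE 0.29) was left out of the rule by its symbol. Other called genes with large changes were left out too. They include the rises of COL6A3 (4.35) and KLK12 (3.90) and the falls of CHIC1 (-2.68) and LIF (-1.66), larger than the falls named next. The falls were the phosphodiesterase gene PDE3B (26.5 ± 8.98 to 13.3 ± 1.55 CPM), the potassium channel gene KCNH7 (-0.95, SE 0.12), DYNLT3 (-0.94, SE 0.20), PAPLN (-0.90, SE 0.14), VAV1 (-0.85, SE 0.18), the collagen-modifying enzyme gene PLOD2 (-0.80, SE 0.16), SPECC1 and NLGN4X (both -0.79). All had an edgeR quasi-likelihood adjusted p between 0.0206 and 0.05. Hypoxia genes (median -0.14, camera adjusted p = 0.00143), YAP and TAZ target genes (-0.20, 0.00685) and Rho and actin genes (-0.15, 0.01) were lower as lists with 0 members called, at 0.345, 0.506 and 0.184 with an estimated correlation. Adjusted over the list alone, 3 hypoxia genes and 3 YAP and TAZ target genes were lower.

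ROR2 itself did not pass in BT-474 (log2 13.57, SE 3.43, edgeR quasi-likelihood adjusted p = 0.0802), since the spread is shared with the SK-BR-3 libraries. Without the library labelled SK-BR-3 vector replicate 1 its SE was 0.29 and its edgeR quasi-likelihood adjusted p 1.02e-10. Of 16014 genes 159 passed an edgeR quasi-likelihood adjusted p of 0.05, 107 higher and 52 lower. With the replicate number as a block 1045 passed, immediate early genes were called lower (camera adjusted p = 0.0364) and 4 identity markers rose. Without the library labelled SK-BR-3 vector replicate 1 the count was 883, with 10 estrogen receptor targets higher and 1 lower. Camera then called 3 more lists higher: noncanonical Wnt and planar polarity genes (median 0.09, camera adjusted p = 0.00142), mitochondrially encoded mRNAs (0.15, 0.00465) and cholesterol synthesis (0.09, 0.0461), at 0.0666, 0.53 and 0.757 with an estimated correlation. Single libraries decided the count in fits that kept the library labelled SK-BR-3 vector replicate 1 and left out 1 other. No other BT-474 or SK-BR-3 library was left out together with it, so how far the 883 depend on single libraries was not tested. In the fits that kept it the count was 1046, 0 and 0 without BT-474 vector replicate 1, 2 or 3, 1, 0 and 0 without BT-474 ROR2 replicate 1, 2 or 3, 91 and 204 without SK-BR-3 vector replicate 2 or 3 and 8, 9 and 11 without SK-BR-3 ROR2 replicate 1, 2 or 3. The estrogen receptor target list was called by camera each time, with 0 members called without BT-474 vector replicate 2 or 3 or any 1 BT-474 ROR2 library and 1 without any 1 SK-BR-3 ROR2 library. The Rho call was lost without BT-474 vector replicate 1 (camera adjusted p = 0.0558).

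In SK-BR-3, the libraries as labelled gave 0 genes by edgeR's quasi-likelihood test out of 16014, beside 2898 at an unadjusted p under 0.05, 627 calls by DESeq2 (87 higher and 540 lower) and 0 by limma-voom. ROR2 itself had log2 1.66 (SE 1.6). Mitochondrially encoded mRNAs were higher (median log2 0.40, camera adjusted p = 1.62e-07, 12 of 13 when adjusted over the list alone), histones higher (0.67, 0.00929) and interferon genes lower (-0.84, 0.000106, 8 of 28 when adjusted over the list alone), each at 0.996 with an estimated correlation. The interferon call was lost without the library labelled SK-BR-3 vector replicate 2 (camera adjusted p = 0.11), and the histone call without the library labelled vector replicate 3 or without ROR2 replicate 1 or 2 (0.146, 0.0556 and 0.136).

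Without the library labelled SK-BR-3 vector replicate 1, ROR2 libraries (n = 3) were set against the other libraries labelled vector (n = 2), and 3773 of 16569 genes passed an edgeR quasi-likelihood adjusted p of 0.05, 1749 higher and 2024 lower. ROR2 stood at 4211 ± 391 against 2.59 ± 0.564 CPM. The collagen genes COL18A1 (1.53 ± 0.0504 to 34.5 ± 7.90 CPM) and COL4A5 (3 counts in all in the vector libraries, ratio 80.3 with a 95% interval of 27.3 to 391), the membrane-cytoskeleton linker gene MSN (1.8 ± 0.556 to 33.9 ± 2.44 CPM), the imprinted RNA H19 (log2 3.86, SE 0.25), ANXA8 (3.48, SE 0.31), SLC2A10 (3.39, SE 0.21) and DPP10 (3.14, SE 0.50) rose. PNMA5 fell from 172 ± 26.2 to 0.114 ± 0.112 CPM and MUC13 from 15.7 ± 3.51 to 0.0654 ± 0.0278 CPM. The fibrinogen gene FGB fell from 41.1 ± 44.2 to 0.298 ± 0.265 CPM. FGG, PIK3CG, C3orf80 and PKIA had 2 or 3 counts in all in the ROR2 libraries, at ratios of 544 (186 to 2643), 238 (65.3 to 1974), 219 (74.6 to 1068) and 161 (54.7 to 786).

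By list, 12 of 13 mitochondrially encoded mRNAs rose in SK-BR-3 without that library (median 0.64, camera adjusted p = 4.36e-13, 12 when adjusted over the list alone), including MT-CYB (0.87, SE 0.09) and MT-ND3 (0.77, SE 0.07). Of 15 histone genes 8 rose and 0 fell (9 rose when adjusted over the list alone), with a median of 1.19 and camera adjusted p = 0.000976. H1-2 went from 13.5 ± 1.31 to 31.0 ± 3.81 CPM and H2BC12 rose by log2 1.31 (SE 0.21). Both lie in a stretch of chromosome 6 whose genes were higher together (25140003 to 27958182, median 0.65). Its median counts these genes too and is not separate from their rise. In the fit with all libraries the mean log2 CPM of the histone list was 1.34 and 0.84 in vector replicates 2 and 3. It was 2.125, 2.31 and 1.35 in the ROR2 libraries, so ROR2 replicate 3 lay near vector replicate 2. These libraries were made with mRNA enrichment, whose effect on histone transcripts was not tested. Of 31 interferon genes 15 fell and 0 rose (19 when adjusted over the list alone; median -1.24, camera adjusted p = 9.9e-07), with BST2, which tethers budding virions, at 39.6 ± 17.3 to 3.96 ± 0.304 CPM and OAS3 at log2 -1.92 (SE 0.21). With an estimated correlation the camera adjusted p was 0.175, 0.623 and 0.405. Among lists not called, CD44 rose (22.6 ± 1.77 to 80.3 ± 21.8 CPM), the ephrin receptor gene EPHB2 fell (22.3 ± 3.59 to 4.47 ± 0.229 CPM). So did the tropomyosin gene TPM2 (56.9 ± 8.65 to 10.9 ± 1.17 CPM), the formin gene DAAM2 (10.8 ± 0.125 to 0.881 ± 0.243 CPM) and CDKN1A, the p21 gene (log2 -1.63, SE 0.20).

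The difference between the ROR2 effects in BT-474 and SK-BR-3 was tested directly. Interferon genes had a higher ROR2 effect in BT-474 by a median of 0.91 on the log2 scale, and hypoxia genes (-0.28) and YAP and TAZ target genes (-0.34) a lower one, at camera adjusted p = 0.00799, 0.00799 and 0.0302. With an estimated correlation these were 0.693, 0.67 and 0.67, and 3 hypoxia genes had a lower effect when adjusted over the list alone. The hypoxia call was lost without the library labelled SK-BR-3 vector replicate 1 (camera adjusted p = 0.0792), the interferon call without the library labelled SK-BR-3 vector replicate 2 (0.246). The YAP and TAZ call was lost without BT-474 vector replicate 2 (0.0656), BT-474 ROR2 replicate 1 (0.0702), SK-BR-3 vector replicate 1 (0.0566) or 2 (0.20) or SK-BR-3 ROR2 replicate 2 (0.0848). The edgeR quasi-likelihood test called 0 of 16014 genes as labelled, beside 3157 at an unadjusted p under 0.05, 782 by DESeq2 and 0 by limma-voom. Without the library labelled SK-BR-3 vector replicate 1 interferon genes differed by a median of 1.44, mitochondrially encoded mRNAs by -0.45 and histones by -1.21 (camera adjusted p = 2.12e-05, 1.82e-05 and 0.0126, each 0.754 with an estimated correlation). The limits given above for the histone list in SK-BR-3 hold here too. The edgeR quasi-likelihood test called 3159 genes without the library labelled SK-BR-3 vector replicate 1. It called 264 without BT-474 vector replicate 1 and 1 without BT-474 ROR2 replicate 1.

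Genes that moved the same way with ROR2 in all 3 lines were counted among 14470 genes tested in each. With the libraries as labelled there were 0, because edgeR's quasi-likelihood test called no gene in SK-BR-3 despite 2898 at an unadjusted p under 0.05, and DESeq2 gave 1. Without the library labelled SK-BR-3 vector replicate 1 there were 15 among 14825: ROR2 itself, ARHGDIG, a Rho GDP-dissociation inhibitor gene, NALF2, SYNPO2L, HYCC1, QDPR, the receptor adaptor gene GRB10, RSU1, ARMT1 and PITRM1 were higher. SLFN11, the urea cycle enzyme gene CPS1, CRABP2, the protease inhibitor gene SPINT1 and BAIAP2L1 were lower. ARHGDIG had log2 fold changes of 1.17 (SE 0.27) in MCF-7, 1.2 (SE 0.23) in BT-474 and 1.47 (SE 0.22) in SK-BR-3, and SLFN11 had -0.73 (SE 0.14), -0.94 (SE 0.24) and -1.71 (SE 0.29). Independent lists of these sizes would share 7.31 genes upwards, beside the 10 counted, and 6.96 downwards, beside the 5 counted. The 10 include ROR2 itself, which the plasmid supplies. Between MCF-7 and BT-474 as labelled, 10 genes rose in both and 10 fell in both, where independent lists would share 14.2 and 7.13, while 8 were higher in MCF-7 and lower in BT-474 (6.75) and 17 the reverse (15). With that library left out the numbers were 63 and 50 in the same direction (65.7 and 55.4) and 82 and 80 in opposite directions (52.0 and 70.0).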

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

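The camera tests of differences between groups and the tests of GC content or gene length and of the same regions in each line were planned, and the other tests in this part were chosen after the result was seen.

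The effect of siWNT11 differed between MCF-7 ROR2 and vector cells by the test of the difference itself for 3 lists: interferon response (median log2 difference -2.30), cholesterol synthesis (-0.11) and mitochondrially encoded mRNAs (0.32), at camera adjusted p = 4.46e-72, 0.000368 and 4.79e-06, and at 0.0702, 0.296 and 0.791 with an estimated correlation. The ROR2 effect differed between BT-474 and SK-BR-3 for hypoxia and glycolysis (-0.28), interferon response (0.91) and YAP and TAZ target genes (-0.34), at camera adjusted p = 0.00799, 0.00799 and 0.0302, and at 0.67, 0.693 and 0.67 with an estimated correlation. The hypoxia call was lost without the library labelled SK-BR-3 vector replicate 1 (camera adjusted p = 0.0792), the interferon call without the library labelled SK-BR-3 vector replicate 2 (0.246), and the YAP and TAZ call without any of 5 libraries, those labelled BT-474 vector replicate 2, BT-474 ROR2 replicate 1, SK-BR-3 vector replicates 1 and 2 and SK-BR-3 ROR2 replicate 2 (0.0656, 0.0702, 0.0566, 0.20 and 0.0848).

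ROR2 at 3989 CPM in the library labelled SK-BR-3 vector replicate 1 was weighed against 3 explanations. On a line from the other vector libraries (0) to the ROR2 libraries (1), over 3772 genes called without it, the library lay at 0.957, where the ROR2 libraries, each left out in turn, lay at 0.924 to 0.959 and the other libraries labelled vector at 0.101 and 0.246. This argues against vector cells in which ROR2 alone rose (0.957 where they would lie near 0), and a mixture with vector RNA is argued against by 26 vector-specific genes, which kept a median of 1.65% of their vector level there and 2.62% in the ROR2 libraries. A single wrong label may be the source, since its position of 0.957 is the one that explanation needs, and no ROR2 library was out of place as a swap within the line would require. Its counts differed from ROR2 replicates 1 and 2 by a chi-square of 4 and 4.02 per gene and from vector replicates 2 and 3 by 63.9 and 61.4, so it was not a copy of another library.

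Neighbouring genes moved together in every ROR2 comparison. Medians over windows of 51 genes spread 2.26 times as widely as in random gene order in MCF-7, 2.48 times in BT-474 and 3.15 times in SK-BR-3 without the doubted library (p = 0.001 each over 1000 permutations, the smallest they can give), with windows at chromosome 6, 24171756 to 26453415, in MCF-7 (median log2 -1.06, 27 of 51 genes called lower), chromosome 17, 55750979 to 61392838, in BT-474 (0.61, 12 higher) and chromosome 7, 100126694 to 102473168, in SK-BR-3 (-0.92, 37 lower). GC content or gene length is argued against, since the lowest ratio was 2.26 after their trend was removed, and the tables go largely against ROR2 acting on the same regions, which needed window correlations of 0.3 between all lines, where MCF-7 gave 0.105 with SK-BR-3 and -0.0501 with BT-474, and BT-474 with SK-BR-3 -0.0874 (0.792 between MCF-7 without siRNA and with siWNT11), although the 0.105 misses the bound of 0.1 set for excluding it, so it is left open. Copy number differences between the stable lines may contribute, but the test as first written counted against them, because the siRNA comparison in ROR2 cells spread by 2.32, no less than the lowest ROR2 ratio of 2.26. After the GC and length trend was removed the siRNA ratios were 1.21 to 1.26. The ROR2 ratios of the 3 lines, with SK-BR-3 taken without the doubted library, were 2.26 to 3.08. This correction was chosen after these values were seen, so copy number stays open and was not measured. The chromosome 6 window in MCF-7 takes in the histone genes named above, and the windows were not tested without histone genes.

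The genes called with siWNT11 in ROR2 cells were weighed by direction. The 22 that fell besides WNT11 all had negative log2 fold changes in vector cells too, though only 12 were called there. Their median was -0.51 there and -0.58 in ROR2 cells, a ratio of 0.882, so off-target action of the siRNA may account for them. Loss of WNT11 signalling was set to be argued against at 0.8 or more, which 0.882 passes, but the quartiles of the genes give ratios of 0.518 to 1.04, WNT11 also stood lower in vector cells (log2 -1.48), and those cells were compared with untreated ones, so it stays open. The 13 that rose lay near the untreated level, with a ratio of 0.158 to their rise over siCTL, below the 0.268 to 0.598 of 20 simulations of unchanged groups, in which the siWNT11 group is likewise shared, so action of the control siRNA may be the source for these as a set. CASP7 among them also rose with siWNT11 in vector cells, where no siCTL was used (log2 1.03, SE 0.15). Only STX12 and G3BP2 of the set were called lower with siCTL than in untreated cells. No second siRNA against WNT11 was analysed here.

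Other splits of the libraries into groups of the same sizes were run as a test of chance. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real split gave 5500 genes in MCF-7 ROR2 (highest other 0; 1 split as large), 36 with siWNT11 in ROR2 cells (0; 1), 2 with siCTL (1; 1), 170 with siWNT11 in vector cells (2177; 2), 159 in BT-474 (1; 1) and 0 in SK-BR-3 by edgeR's quasi-likelihood test (820; 10), beside 2898 at an unadjusted p under 0.05, 627 by DESeq2 and 0 by limma-voom. The split with 2177 set siWNT11 replicates 1 and 3 and vector replicate 3 against the others, and that with 820 put the library labelled SK-BR-3 vector replicate 1 with ROR2 libraries, so both point to a structure of the samples. Where the numbers pair the libraries, the splits that part every pair (4, with the real one) gave 0 genes apart from the real one. Lists called numbered 8 in MCF-7 ROR2 (highest other 10; 3 splits as large), 0 with siWNT11 in ROR2 cells (9; 10), 6 with siCTL (9; 4), 5 with siWNT11 in vector cells (6; 5), 5 in BT-474 (7; 4) and 3 in SK-BR-3 (6; 9). Among the splits that part every pair the highest other number of lists was 1 with siWNT11 in ROR2 cells, 3 with siCTL, 5 with siWNT11 in vector cells and 4 in BT-474, so the real split was the highest with siCTL and in BT-474, tied in vector cells and not the highest in ROR2 cells. Over 100 drawn splits chance is not excluded for the lists called in the MCF-7 interaction (3 lists, highest other 10, 88 splits as large). Nor is it excluded for those in the difference between BT-474 and SK-BR-3 (3 lists, 8, 71). Their gene counts of 0 decide nothing, because every split gives at least 0 (highest other 565 and 393, 100 splits as large in each). The same holds for the 0 genes in SK-BR-3. For the 0 calls shared by 3 lines (highest other 0, 100 of 100) and the 10 opposed calls (0, 1 of 100) the splits decide nothing, because no other combination drawn had calls in every comparison.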

How the results depend on the processing

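The fits without the third replicates, and every use of results without the library labelled SK-BR-3 vector replicate 1 beyond its leave-one-out count, were chosen after the data were seen; the other alternatives were planned. Counts within 1.5 times of the reported one are not listed, and the cause of a change was not tested unless the setting itself (fewer libraries, a stricter threshold) gives it. Without a filter on low counts the number of genes called was 11 with siWNT11 in ROR2 cells, 1 with siCTL, 19 in the MCF-7 interaction, 543 in BT-474, 884 in SK-BR-3, 774 for the difference between those lines and 2 opposed calls (1 same-way), and at a minimum count of 50 it was 9 with siCTL and 1 in the interaction. DESeq2 called 93, 154, 420 and 75 genes with siWNT11 in ROR2 cells, siCTL, siWNT11 in vector cells and the interaction, 944 in BT-474, 627 in SK-BR-3, 782 for their difference, 1 shared by 3 lines and 19 opposed beside 19 same-way calls (10 and 4 in the reported fit), but it made 37 false calls in the simulated MCF-7 ROR2 comparison and 26 in the BT-474 one. Limma-voom called 5 with siCTL, 1 in the interaction and 430 in BT-474. Opposed and same-way calls were 6 and 2 with RLE size factors and 5 and 3 without mitochondrial and the 20 most abundant genes, where the interaction gave 2. With only the groups compared in the fit, 0 genes were called with siWNT11 in ROR2 cells, siCTL or siWNT11 in vector cells by edgeR's quasi-likelihood test (unadjusted p under 0.05 in the full fit: 711, 1561 and 1836), 529 in BT-474 and 0 were opposed or same-way. Without the third replicates the counts were 3, 1 and 0 for those siRNA comparisons and 0 opposed (1 same-way). Untreated ROR2 cells as control gave 14 with siWNT11, 2 opposed and 3 same-way. At an adjusted p of 0.01 there were 2979 in MCF-7 ROR2, 11 and 59 with siWNT11 in ROR2 and vector cells, 0 in BT-474 and 2 opposed (1 same-way), and with a log2 fold change of at least 1 there were 2054, 6, 0 with siCTL, 111 in vector cells, 42 in BT-474 and 1 opposed (0 same-way).

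With the replicate number as a block the counts were 59 with siWNT11 in ROR2 cells, 76 with siCTL, 395 (8 lists) with siWNT11 in vector cells, 1045 in BT-474 and 20 opposed (10 same-way), and where the numbers pair the libraries it changed no other call than those given beside the results. In the other comparisons not every pair of libraries with the same number deviated together at a correlation above 0.1. Pairs above it were 2 of 3 in MCF-7 ROR2 (lowest 0.00942) and 1 of 3 in SK-BR-3 (0.0471). They were 16 of 18 in the MCF-7 interaction (-0.0162) and 4 of 18 in the difference between BT-474 and SK-BR-3 (-0.0862). There the block gave 7628, 43, 0 and 505 genes. It moved the YAP and TAZ difference between BT-474 and SK-BR-3 to camera adjusted p = 0.0507. As a hint from the data, 26 of the 27 libraries correlated best with their own number, so the numbers may pair libraries in these comparisons too. With an estimated correlation camera called 0 lists in MCF-7 ROR2, with siCTL, in the interaction, in SK-BR-3 and for the difference between lines, 1 with siWNT11 in vector cells and 2 in BT-474. Leaving out 1 library at a time gave 3748 to 6203 genes in MCF-7 ROR2, 9 to 13 with siWNT11 in ROR2 cells, 1 to 4 with siCTL, 44 to 372 with siWNT11 in vector cells, 0 to 66 in the interaction, 0 to 1046 in BT-474, 0 to 3773 in SK-BR-3, 0 to 3159 for their difference, 0 to 15 shared and 1 to 10 opposed, and 8 to 9, 0 to 4, 4 to 7, 4 to 6, 3 to 6, 4 to 8, 2 to 4 and 1 to 6 lists in the first 8 of these. Of 127 called results for named genes, RLE lost 4, no filter 10, DESeq2 1, limma-voom 10, the block 0 and leaving out some library 44, and 0 reversed. In simulations with 3 libraries per group and few changed genes, most genes changed 1.5-fold were missed. Of such genes 19.4% were called in the simulated MCF-7 ROR2 comparison and 29.9% in the BT-474 one. The share may differ where many genes change, as in the real MCF-7 ROR2 comparison, which was not simulated.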

Other observations

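The counts in this part were chosen after the data were seen.

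NF-kB target genes separated MCF-7 vector and ROR2 cells more evenly than the hypoxia list did. Their mean log2 CPM was 3.07, 2.95 and 3.15 in the vector libraries and 1.40, 1.52 and 1.55 in the ROR2 libraries, and 1.39, 1.78 and 1.8 in ROR2 cells given siWNT11. ROR1, the paralog of ROR2, had 5 counts in all in MCF-7 vector cells and 0.25 ± 0.0453 CPM (n = 3) in ROR2 cells, and 1.11 ± 0.32 and 1.67 ± 0.628 CPM in BT-474 vector and ROR2 cells. ESR1 was 1.77 ± 0.241 CPM in the libraries labelled SK-BR-3 vector and 0.834 ± 0.119 in SK-BR-3 ROR2 cells, and 1.92 ± 0.0115 (n = 2) without the library labelled SK-BR-3 vector replicate 1.

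Pairs of lines shared calls in both the same and the opposite direction. Without the library labelled SK-BR-3 vector replicate 1, MCF-7 and SK-BR-3 shared 342 rises (independent lists would share 240.2), 329 falls (289), 322 genes higher in MCF-7 and lower in SK-BR-3 (271) and 278 lower in MCF-7 and higher in SK-BR-3 (256). BT-474 and SK-BR-3 shared 63 rises (51.7) and 69 falls (48.0), while 97 genes were lower in BT-474 and higher in SK-BR-3 (41.5) and 75 the reverse (59.9). These latter comparisons share a fit but no library.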
